A study of Ovis aries with 6 samples.

How the data were processed

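RNA was sequenced from perirenal adipose tissue of 3 Merino fetuses at 132 days post conception and 3 lambs, none of them treated per the labels. The titles of the 3 lamb samples carry the letters VEH, whose meaning is not given in the sources used here; if they stand for a vehicle, that treatment would coincide with stage. Per the labels, tissue was removed within 10 minutes of euthanasia and frozen, RNA was extracted with Trizol and RNeasy columns, treated with DNase and had integrity numbers above 9. Libraries were made from 5 µg of total RNA with a TruSeq RNA kit, and the 6 libraries were run together as single-end 50 bp reads on 1 flowcell, with a mean of about 33.2 M reads each. The authors mapped reads to Ensembl gene models of the sheep assembly Oar v3.1 in CLC Genomics Workbench; filter settings for reads, the treatment of reads with several placements and whether counting was stranded are not given in the sources used here. Counts of genes that overlap on opposite strands can therefore hold reads of either.

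The deposited tables give read counts per gene and library as whole numbers, and the unit of these columns is counts. The authors also give RPKM (read counts scaled by gene length and library size) as a mean per stage, and the p-value, adjusted p-value and signed linear fold score of their own edgeR comparison. RPKM means were used for description only, since for some genes the reads behind them differ from those in the count columns. The 12 per-library RPKM columns of both tables were not used, because a header among them repeats the name of fetal or lamb sample 3 where sample 2 would stand. Positions are those of the full table, counted from 1 on Oar v3.1; the prefiltered table has starts lower by 1.

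The full table holds 24390 genes, of which 6258 have an identifier only and 185 symbols stand at more than 1 locus. In it 6130 genes had 0 counts everywhere, 17010 had counts in both stages, 720 in fetal libraries only and 530 in lamb libraries only. The prefiltered table holds the 17010 genes; 3 of them (MARCH2, MARC2 and a copy of RPL17) differ between the tables, and 1 has no Ensembl identifier there. Symbols are those of the tables, with older names matched to the lists by hand, so that PPARG2, HBBB and MT2 stand for PPARG, HBB and MT2A.

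Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, 13624 in all, libraries were scaled by TMM, and the stages were compared by the quasi-likelihood F test without covariates. TMM factors were 0.875, 0.723 and 0.956 for the fetal and 1.18, 1.21 and 1.16 for the lamb libraries. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The SE of a log2 difference is its size divided by the root of F. CPM values are counts scaled to the TMM-adjusted library size. For a gene with 0 counts in a stage, the fold is a bound against 3 counts over the group, and for 1 to 3 counts the ratio has a 95% interval that covers counting error only. A count of 0 allows up to 0.157, 0.159 and 0.171 CPM in the fetal and 0.174, 0.189 and 0.174 CPM in the lamb libraries before TMM scaling.

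Before the data were examined, 34 gene lists were fixed. Those of tissue biology were brown adipocyte identity and heat production, beige adipocytes, white adipocytes, general adipocyte genes, nuclear respiratory chain subunits, mitochondrial genome genes, mitochondrial ribosome and tricarboxylic acid cycle. They also covered fatty acid oxidation, lipogenesis, lipolysis and lipid droplets, cholesterol synthesis, glycolysis and hypoxia, cell cycle and extracellular matrix. The last of this kind were imprinted genes, fetal growth regulators, HOX genes, glucocorticoid action, clock and interferon-induced genes. Immediate early genes, which move with tissue handling, were a list of sample quality. Those of other cell types were macrophages, T and NK cells, B and plasma cells, endothelium, pericytes and smooth muscle, fibroblasts and preadipocytes, skeletal muscle, adrenal, kidney, red cells, Schwann cells and nerve, and mesothelium. Each list was tested with limma 3.58.1 by camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and by fry, each adjusted over the lists. Camera compares a list with all other genes, and fry does not. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, not from the genes, which leaves it little power here.

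Genes to name were also fixed by a rule. It took 11 genes whatever their result (UCP1, CIDEA, PPARGC1A, PRDM16, DIO2, ADRB3, LEP, ADIPOQ, PPARG, IGF2 and DLK1) and the 10 largest increases and 10 largest decreases among called genes with a symbol, at least 5 CPM in the higher stage and no overlap between the stages. From each list it took up to 3 called members with the largest change in the direction most called members took and up to 1 in the other, at 1 CPM or more. Members of that kind are quoted as examples, not all of them. Other genes were chosen after their values were seen, as is said where they appear.

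Alternatives fixed beforehand were DESeq2 size factors, upper quartile factors and library totals in place of TMM; no count filter beyond 1 count, at least 5 CPM in 3 libraries, or the genes of the prefiltered table; DESeq2 1.42.0, the edgeR exact test and limma-voom in place of the quasi-likelihood test; leaving out the 10 most abundant genes; the replicate number as a block; and leaving out each library in turn. Leaving out the mitochondrial genome genes, or the genes found in fetal library 1 alone, was added after the data were seen. The test was tried on counts with 200 genes simulated as changed. Of 40 genes each, it recovered 90.0% at 4-fold, 32.5% at 2-fold and 0% at 1.5-fold increases, 40.0% and 72.5% at decreases to 0.5 and 0.25 of the level, and 6.93% of its calls were false.

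Shares of counts were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 is 0.1. The 10 possible splits of the 6 libraries in 3 and 3 were each fitted like the stages. Genes of 1 library alone were defined as those at 5 CPM or more and at least 8-fold above every other library. Tables were prepared and summaries made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9. The results of 2 genes chosen by the rules for single genes are not reported here.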

Results

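Gene expression was measured by RNA sequencing in perirenal adipose tissue, the fat around the kidney, of pure-bred Merino sheep. There were 3 fetuses at 132 days post conception, with term at 150 days, and 3 lambs. The lamb age is given in 3 ways in the labels, as 80 days after birth, as 89 days old (89 ± 7 days in the growth protocol) and as 12 weeks. Each library came from a separate animal, so n = 3 per stage throughout. The fetal libraries held 19150428, 18813744 and 17535892 counts and the lamb libraries 17232160, 15907128 and 17263780, and between 16345 and 16907 genes had at least 1 count in a library. The stages separated along the first principal component, which held 74.7% of the variance. Spearman correlations across genes lay between 0.974 and 0.982 within a stage and between 0.878 and 0.906 across stages. Values per gene are CPM, counts scaled to library size with TMM factors, given as mean ± SD. Fold changes are log2 differences, lamb minus fetal, ± SE, with adjusted p-values from edgeR.

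The comparison of lambs with fetuses addresses which transcripts differ in perirenal fat between the stages. This fat is held to be brown-like before birth and white some weeks after it. By gene lists tested with a preset inter-gene correlation, genes of heat production, of mitochondria and of proliferation were lower in lambs. General adipocyte genes, genes of glucocorticoid action, and macrophage, extracellular matrix and fibroblast genes were higher. Immediate early genes, which also move with tissue handling, were higher too. Red cell genes were lower. So was the mesothelium list, through 4 genes that urothelium expresses too, while its member WT1 was at 1.30. The call of the mesothelium list was lost in several settings. With a correlation estimated from the data none of the lists passed, the smallest adjusted p being 0.513. That setting has little power with 6 libraries, so a failure to pass it says little about a list. The glucocorticoid list, at 0.513, had an estimated correlation of -0.023, below the preset 0.01. Estimates for other called lists were far above the preset, at 0.746 for the nuclear respiratory chain, 0.712 for the tricarboxylic acid cycle and 0.586 for macrophages. For such lists the preset can understate how far genes move together, and camera p-values with it can be too small. UCP1, the uncoupling protein through which brown adipocytes make heat (ENSOARG00000012510, chromosome 17, 16847682 to 16853677 on Oar v3.1), fell from 1633 ± 530 CPM in fetuses to 476 ± 77.2 CPM in lambs. Its log2 difference was -1.78 ± 0.27 (adjusted p = 0.00154), with all 3 lamb values below all 3 fetal values. Of 13624 genes tested, 6095 passed the threshold, 3002 higher and 3093 lower in lambs, and 3122 of them differed by more than 2-fold, 1366 higher and 1756 lower. Scaling by library totals alone moved the median log2 difference of all genes up by 0.47, and 79.3% of the genes called were then higher in lambs, against 49.3% with TMM. Under it 4460 of the 6095 calls were kept and 0 changed direction, and UCP1 was then at -1.26.

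Among the 27 tested genes of brown adipocyte identity and heat production, 16 were lower, 3 higher and 8 not past the test, with a median log2 difference of -1.78 (camera adjusted p = 2.08e-04; adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, 17 were lower and 3 higher. DIO2, which converts thyroxine to the active thyroid hormone (ENSOARG00000002802, chromosome 7, 88484098 to 88493094), fell from 23.6 ± 4.52 to 0.186 ± 0.0812 CPM, a log2 difference of -6.94 ± 0.31 (adjusted p = 2.29e-05). COX7A1, a cytochrome c oxidase subunit of muscle and brown fat (chromosome 14, 45928308 to 45929037), fell from 201.0 ± 54.8 to 2.86 ± 0.357 CPM (log2 difference -6.13 ± 0.26). PPARGC1B, a coactivator of mitochondrial genes, fell by 4.49 ± 0.20 on the log2 scale. PRDM16, a transcription factor of brown adipocyte fate, fell by 1.86 ± 0.26, and the adrenergic receptor gene ADRB3 fell by 1.46 ± 0.31. Genes listed as brown also rose. The transcription factor gene IRF4 (ENSOARG00000003822, chromosome 20, 50972069 to 50985668) went from 1.71 ± 0.85 to 676 ± 207 CPM, the largest increase among the named genes (log2 difference 8.62 ± 0.46, adjusted p = 4.20e-05). The potassium channel gene KCNK3 (chromosome 3, 33714717 to 33753471) went from 1.37 ± 0.16 to 108 ± 10.9 CPM (log2 difference 6.28 ± 0.16).

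CIDEA, a lipid droplet protein of brown fat, was at 80.1 ± 12.8 CPM in fetuses and 63.1 ± 21.4 CPM in lambs (log2 difference -0.34 ± 0.26, adjusted p = 0.311). The CIDEA difference was -0.58 without lamb library 1, -0.10 without lamb library 2 and 0.13 with scaling by library totals, and it did not pass under any alternative. PPARGC1A, the main coactivator of mitochondrial biogenesis, had a log2 difference of -1.07 ± 0.39 and did not pass the test (adjusted p = 0.0583). Without lamb library 3, PPARGC1A was at -1.60 with adjusted p = 0.00797. It also passed with upper quartile factors, a filter of at least 5 CPM in 3 libraries, DESeq2, the exact test or limma-voom. PPARGC1A was at -0.58 with scaling by library totals (adjusted p = 0.167) and at -0.75 without lamb library 2, and over all alternatives its adjusted p ranged from 0.00522 to 0.171. The 9 tested beige adipocyte markers had 3 lower, 1 higher and 5 not past the test (median -0.23, between -0.30 and -0.13 on leaving out 1 library; camera adjusted p = 0.599), with the same counts adjusted over the list alone. Among them TMEM26 fell by 2.02 ± 0.38. FBXO31 rose by 0.38 ± 0.12, a call lost on leaving out any 1 of the 6 libraries (adjusted p between 0.0524 and 0.116, against 0.00593 to 0.116 over all alternatives).

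**Figure D1:**
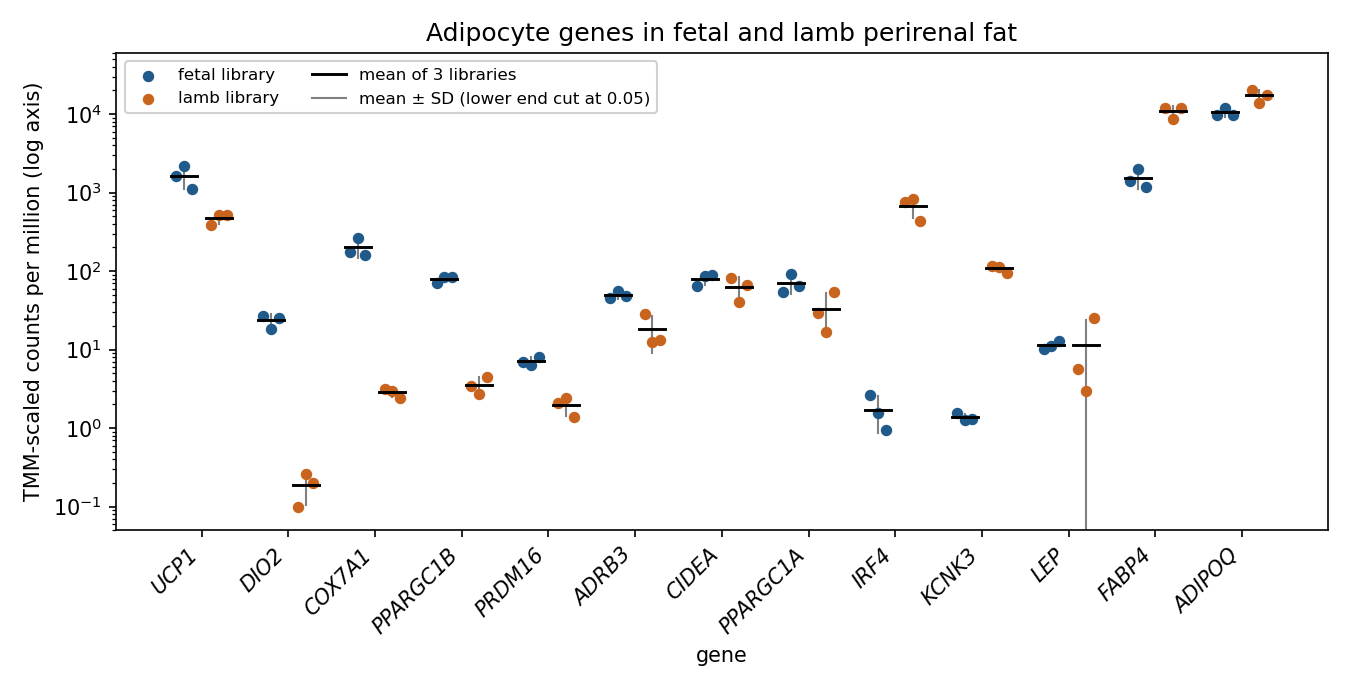
TMM-scaled CPM on a log axis for 13 adipocyte genes, 1 point per library, 3 fetal (blue) and 3 lamb (orange), with the mean as a horizontal line and the SD as a vertical line. UCP1, DIO2, COX7A1 and PPARGC1B lie lower in all lamb libraries and IRF4, KCNK3 and FABP4 higher, while the lamb values of LEP are spread around the fetal mean.

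Genes of the respiratory chain fell together. All 55 tested nuclear genes for respiratory complex and ATP synthase subunits were lower in lambs, with a median log2 difference of -1.99 (camera adjusted p = 1.88e-23; adjusted p = 0.578 with an estimated correlation), and all 55 also passed when adjusted over the list alone. All 13 protein genes of the mitochondrial genome were lower as well (median -2.54, camera adjusted p = 6.92e-06; adjusted p = 0.578 with an estimated correlation), again with 13 adjusted over the list alone. ATP5G1, a subunit of the ATP synthase ring, fell from 539 ± 93.9 to 40.9 ± 18.8 CPM (log2 difference -3.72 ± 0.34), and cytochrome c, CYCS, fell by 3.17 ± 0.50. COX1, a mitochondrially encoded subunit of cytochrome c oxidase, fell by 2.94 ± 0.35 and was the most abundant gene in every library. Mitochondrial genome genes together held 34.5%, 40.7% and 27.5% of the counts in the fetal libraries and 8.02%, 7.37% and 8.29% in the lamb libraries, with 95% Wilson intervals, for counting error only, of 34.44 to 34.48%, 40.68 to 40.73%, 27.49 to 27.53%, 8.01 to 8.03%, 7.36 to 7.38% and 8.27 to 8.30%. The means were 34.2 ± 6.60% and 7.89 ± 0.47%, a difference for which the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows.

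Other mitochondrial genes followed. The lists are not independent, because some share members. COX7A1 is in the brown adipocyte and respiratory chain lists, and CPT1B in the brown adipocyte and fatty acid oxidation lists. SDHA, SDHB, SDHC and SDHD were listed under both the respiratory chain and the tricarboxylic acid cycle. Of 60 genes of the mitochondrial ribosome, 49 were lower, 11 did not pass and 0 were higher (median -0.81, camera adjusted p = 1.37e-11; adjusted p = 0.578 with an estimated correlation), with MRPL12 at -2.72 ± 0.21. Of 19 genes of pyruvate dehydrogenase and the tricarboxylic acid cycle, 18 were lower, 1 did not pass and 0 were higher (median -1.72, camera adjusted p = 2.68e-09; adjusted p = 0.578 with an estimated correlation). IDH2 fell from 666 ± 211 to 24.2 ± 1.48 CPM (log2 difference -4.78 ± 0.26), IDH3A fell by 3.61 ± 0.27 and citrate synthase, CS, fell by 3.07 ± 0.23. Of 20 genes of fatty acid oxidation, 13 were lower, 1 higher and 6 not past the test (median -1.33, camera adjusted p = 4.30e-05; adjusted p = 0.578 with an estimated correlation), and 15 were lower and 1 higher adjusted over the list alone. CPT1B, which loads fatty acids onto carnitine, fell by 3.07 ± 0.29, and ACADVL fell from 3134 ± 376 to 602 ± 92.0 CPM (log2 difference -2.38 ± 0.19). The member that rose, ACSL1 (log2 difference 2.00 ± 0.21), activates fatty acids for both oxidation and storage. Adjusted over the list alone, the ribosome and cycle lists kept 49 and 18 lower.

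Genes of mature adipocytes in general were higher in lambs, 15 of 21 tested, with 2 lower and 4 not past the test (median 1.39, camera adjusted p = 2.51e-04; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone the counts were again 15 and 2. FABP4, the adipocyte fatty acid binding protein (chromosome 9, 57536525 to 57541042), rose from 1532 ± 428 to 10928 ± 1875 CPM (log2 difference 2.83 ± 0.27). LPIN1, a phosphatidate phosphatase of triacylglycerol synthesis, rose by 3.32 ± 0.30, and CIDEC, a protein of large lipid droplets, by 2.58 ± 0.15. PPARG, the adipogenic nuclear receptor, listed as PPARG2, rose by 0.66 ± 0.15 (adjusted p = 0.00932). The insulin-responsive glucose transporter gene SLC2A4 fell by 2.02 ± 0.31. The adipokine gene ADIPOQ rose from 10496 ± 1240 to 17311 ± 3171 CPM (log2 difference 0.72 ± 0.22, adjusted p = 0.0309). Its call was lost without fetal library 1 (adjusted p = 0.137), fetal library 3 (0.109), lamb library 1 (0.0959) or lamb library 3 (0.0572) and with the replicate number as a block (0.103), and over all alternatives adjusted p ranged from 2.76e-04 to 0.137.

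Genes reported as enriched in white adipocytes did not move as a group. Of 17 tested, 6 were higher, 5 lower and 6 not past the test, the same adjusted over the list alone (median 0.30, between -0.15 and 0.44 on leaving out 1 library; camera adjusted p = 0.774, with fry pointing down). SNCG rose by 5.02 ± 0.55 and the matrix protein gene DPT by 3.50 ± 0.36, while the natriuretic peptide clearance receptor gene NPR3 fell by 4.96 ± 0.28. LEP, which encodes leptin, was at 11.3 ± 1.30 CPM in fetuses and 11.3 ± 12.2 CPM in lambs (adjusted p = 0.997). Lamb library 3 held most of the LEP counts of its stage, and without it LEP was at -1.39 with adjusted p = 0.0123 (range over all alternatives 0.0123 to 1).

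Of 23 genes of fatty acid and triacylglycerol synthesis, 10 were lower, 3 higher and 10 not past the test, with 11 and 3 adjusted over the list alone (median -1.06, camera adjusted p = 0.0541). The list passed without fetal library 1 (adjusted p = 0.022) and without lamb library 3 (adjusted p = 0.00182). It also passed with DESeq2 size factors, library totals, no filter beyond 1 count, the genes of the prefiltered table or the replicate number as a block, and over all alternatives adjusted p ranged from 0.00182 to 0.825. IDH1 fell by 2.59 ± 0.35 and SREBF1, a transcription factor of lipogenic genes, by 1.99 ± 0.27, whereas THRSP, a lipogenic protein induced by thyroid hormone, rose from 15.8 ± 3.53 to 559 ± 271 CPM (log2 difference 5.15 ± 0.42). Of 19 genes of lipolysis and lipid droplets, 8 were higher, 5 lower and 6 not past the test, with 8 and 5 adjusted over the list alone (median 0.20, camera adjusted p = 0.305). That list passed with the DESeq2 Wald test (adjusted p = 0.0309), and its median lay between 0.10 and 0.50 on leaving out 1 library. Its members FABP4 and CIDEC rose by 2.83 ± 0.27 and 2.58 ± 0.15, as given above, while the lipase inhibitor gene G0S2 fell by 2.82 ± 0.47. Of 22 cholesterol synthesis genes, 4 were higher, 4 lower and 14 not past the test, with 3 and 4 adjusted over the list alone (median 0.12, between -0.01 and 0.28 on leaving out 1 library; camera adjusted p = 0.928), and INSIG1 rose by 1.58 ± 0.20. Of 27 genes of glycolysis and the hypoxia response, 8 were higher, 12 lower and 7 not past the test, with 10 and 12 adjusted over the list alone. Their median was -0.01, between -0.10 and 0.09 on leaving out 1 library, and their mean 0.21 (camera adjusted p = 0.987). PFKFB3, which makes the activator of phosphofructokinase, rose from 7.44 ± 2.05 to 491 ± 56.4 CPM (log2 difference 6.04 ± 0.25), and the liver-type phosphofructokinase gene PFKL fell by 2.63 ± 0.29.

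The 10 largest increases among called genes with a symbol, at least 5 CPM in lambs and no overlap between the stages were IRF4, SLC27A6, MTUS2, CYP4B1, SLC7A8, ACMSD, PLAUR, KCNK3, NR4A3 and PFKFB3. The fatty acid transporter gene SLC27A6 rose from 0.568 ± 0.257 to 177 ± 74.7 CPM (log2 difference 8.30 ± 0.48), and MTUS2 from 0.675 ± 0.362 to 118 ± 15.01 CPM (7.40 ± 0.30). The remaining ones rose by 7.35 ± 0.99 (CYP4B1), 7.16 ± 0.65 (SLC7A8), 6.44 ± 0.54 (ACMSD), 6.40 ± 0.64 (PLAUR) and 6.08 ± 0.31 (NR4A3). Among the 10 largest decreases were UPK3A, KRT7, NMRK2, KRT5, UPK1A, DIO1, KRT15, KRT13 and DIO2. NMRK2, a nicotinamide riboside kinase (chromosome 5, 17629206 to 17633291), fell from 203 ± 107 to 0.338 ± 0.135 CPM (log2 difference -9.21 ± 0.60), and the deiodinase gene DIO1 from 137 ± 78.3 to 0.642 ± 0.244 CPM (-7.72 ± 0.64). UPK3A, UPK1A, KRT7, KRT5, KRT15 and KRT13 are genes of uroplakins and keratins.

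Proliferation genes were lower in lambs, 33 of 42 tested, with 3 higher and 6 not past the test (median -1.36, camera adjusted p = 9.63e-07; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 34 were lower and 3 higher. CDC6, needed to start DNA replication, fell by 2.91 ± 0.38, the ribonucleotide reductase gene RRM2 by 2.65 ± 0.39 and DLGAP5 by 2.31 ± 0.35, while the mitotic kinase gene AURKA rose by 1.33 ± 0.24. Of 12 imprinted genes, 5 were lower, 1 higher and 6 not past the test, with the same counts adjusted over the list alone (median -0.52, camera adjusted p = 0.305). PEG10 fell by 1.64 ± 0.21, MEST by 1.49 ± 0.21 and IGF2 by 1.33 ± 0.28, and GRB10 rose by 1.65 ± 0.18. DLK1, which holds back adipocyte differentiation, was at 91.9 ± 33.9 CPM in fetuses and 39.2 ± 27.1 CPM in lambs and did not pass the test (log2 difference -1.23 ± 0.61, adjusted p = 0.138). DLK1 passed with the edgeR exact test (adjusted p = 0.0293) and with the replicate number as a block (adjusted p = 0.0209), and its difference was -0.75 without lamb library 2. Of 16 fetal growth regulators, 5 were higher, 3 lower and 8 not past the test, with 6 and 4 adjusted over the list alone; their median was -0.15, between -0.22 and 0.10 on leaving out 1 library, while camera pointed up (adjusted p = 0.774). The growth hormone receptor gene GHR rose by 2.98 ± 0.17 and the prolactin receptor gene PRLR fell from 36.3 ± 5.78 to 0.518 ± 0.142 CPM (log2 difference -6.11 ± 0.23). Of 24 HOX genes, 8 were lower, 1 higher and 15 not past the test, as they were adjusted over the list alone (median -0.35, camera adjusted p = 0.156), with HOXC10 at -1.51 ± 0.27.

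Genes of glucocorticoid action were higher, 10 of 15 tested, with 1 lower and 4 not past the test, also when adjusted over the list alone (median 1.29, camera adjusted p = 4.51e-04; adjusted p = 0.513 with an estimated correlation). PDK4, which inhibits pyruvate dehydrogenase (chromosome 4, 12768760 to 12781448), rose from 109 ± 53.4 to 4096 ± 556 CPM (log2 difference 5.23 ± 0.41), FKBP5 rose by 4.75 ± 0.39 and the metallothionein gene MT2A, listed as MT2, by 4.76 ± 0.46, whereas ANGPTL4 fell by 2.17 ± 0.20. Immediate early genes, which respond within minutes to stimulation or tissue handling, were higher in lambs for 18 of 19 tested, with 0 lower and 1 not past the test, also adjusted over the list alone (median 2.25, camera adjusted p = 2.68e-09; adjusted p = 0.563 with an estimated correlation). NR4A3 rose by 6.08 ± 0.31 and ATF3 by 4.30 ± 0.23. FOSL1 had 3 counts in the fetal and 291 in the lamb libraries, a ratio of 76.7 with a 95% counting interval of 26.0 to 374. Any difference in tissue handling between the stages would coincide with age and was not tested. Of 16 clock genes, 4 were lower, 2 higher and 10 not past the test, with 3 and 2 adjusted over the list alone; their median was 0.06, between -0.18 and 0.07 on leaving out 1 library, while camera pointed down (adjusted p = 0.839). CRY2 fell by 1.69 ± 0.12 and PER3 rose by 1.14 ± 0.17. Of 20 interferon-induced genes, 3 were lower, 1 higher and 16 not past the test, with 2 lower and 0 higher adjusted over the list alone (median -0.85, camera adjusted p = 0.072), and RSAD2 fell by 1.56 ± 0.29. That list passed without fetal library 1 (adjusted p = 0.0219) and without lamb library 2 (adjusted p = 9.65e-04), and also with library totals or no filter beyond 1 count, while its median was -0.56 without lamb library 3 (adjusted p = 0.263), against a range of 9.65e-04 to 0.825 over all alternatives.

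**Figure D2:**
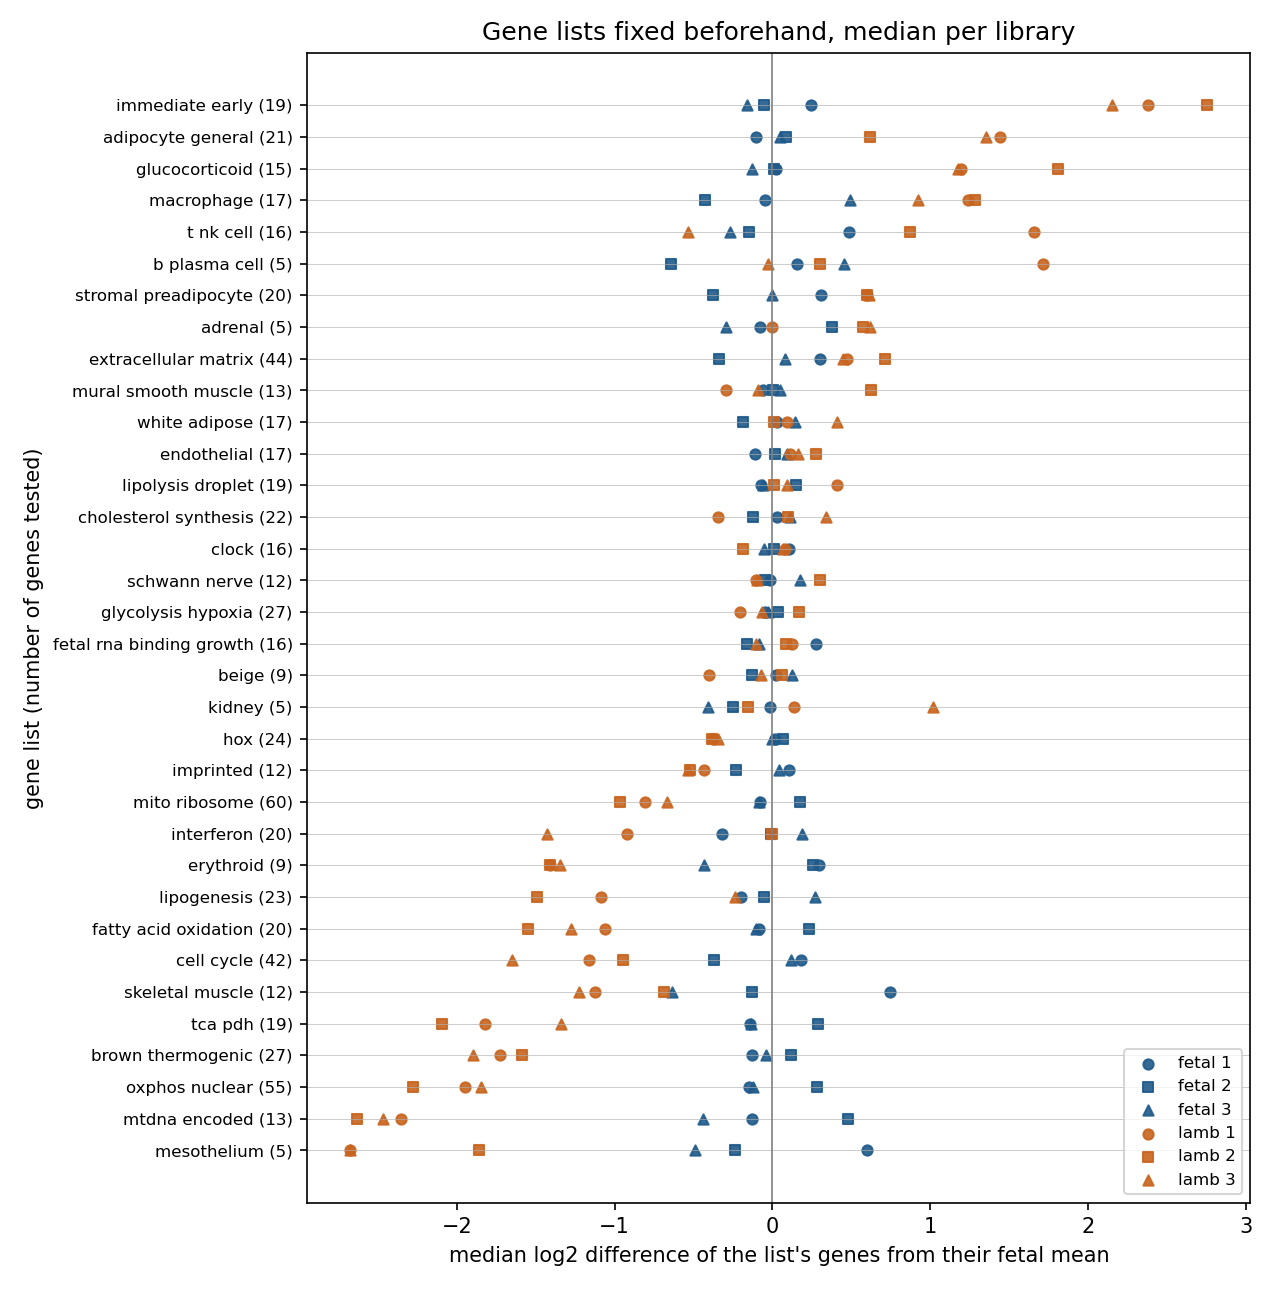
Median log2 difference of each list's tested genes from their own fetal mean, in 1 point per library, fetal in blue and lamb in orange. Respiratory chain, mitochondrial genome, tricarboxylic acid cycle and brown adipocyte lists lie left of all fetal points in the 3 lamb libraries, and immediate early, glucocorticoid and general adipocyte lists lie right of them.

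Some lists of other cell types also differed by stage. With the preset correlation camera called the macrophage, fibroblast, red cell and mesothelium lists, and no other list of that kind. The extracellular matrix list, one of tissue biology, is given beside them. Counts of called members are to be read against 6095 of 13624 genes called in all. Of 17 macrophage genes, 11 were higher, 1 lower and 5 not past the test, also adjusted over the list alone (median 1.16, camera adjusted p = 6.08e-04; adjusted p = 0.682 with an estimated correlation). The mannose receptor gene MRC1 rose from 57.6 ± 14.1 to 993 ± 163 CPM (log2 difference 4.11 ± 0.25) and CD14 by 2.46 ± 0.19. SIGLEC1 fell by 1.94 ± 0.40, and by 1.29 without fetal library 3. Of 44 extracellular matrix genes, 18 were higher, 2 lower and 24 not past the test, with 19 and 2 adjusted over the list alone (median 0.58, camera adjusted p = 0.00175; adjusted p = 0.723 with an estimated correlation). THBS1 rose by 3.73 ± 0.54, TIMP2 by 2.76 ± 0.23 and TIMP3 by 2.28 ± 0.20. Of 20 fibroblast and preadipocyte genes, 7 were higher, 1 lower and 12 not past the test, also adjusted over the list alone (median 0.65, camera adjusted p = 0.0317; adjusted p = 0.703 with an estimated correlation). GSN rose by 1.97 ± 0.21 and CD34 fell by 1.30 ± 0.15. The call of that list was lost without fetal library 2 (adjusted p = 0.0559) and with scaling by library totals (adjusted p = 0.104), DESeq2 or the exact test, in a range of 0.00517 to 0.703 over all alternatives.

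Red cell genes were lower, 5 of 9 tested, with 4 not past the test and 0 higher, also adjusted over the list alone (median -1.04, camera adjusted p = 0.0246; adjusted p = 0.578 with an estimated correlation). Their median was -2.26 without fetal library 3 and -2.19, -1.99 and -2.27 without lamb library 1, 2 or 3, and the call was lost with a filter of at least 5 CPM in 3 libraries (adjusted p = 0.372, in a range of 8.55e-04 to 0.578 over all alternatives). The beta-globin gene, listed as HBBB, fell from 701 ± 463 to 21.3 ± 6.24 CPM (log2 difference -5.04 ± 0.54), and HEMGN had 151 fetal and 2 lamb counts, a ratio of 95.4 with a 95% counting interval of 26.0 to 795. Of 17 endothelial genes, 5 were higher, 3 lower and 9 not past the test (median 0.22, between 0.12 and 0.25 on leaving out 1 library; camera adjusted p = 0.470). LYVE1, a marker of lymphatic vessels and resident macrophages, rose by 1.94 ± 0.24 and TIE1 fell by 1.20 ± 0.19. Of 13 pericyte and smooth muscle genes, 3 were higher, 2 lower and 8 not past the test (median 0.32, but -0.19 without lamb library 2; camera adjusted p = 0.607), with MCAM at 2.04 ± 0.15. Of 12 Schwann cell and nerve genes, 2 were higher, 1 lower and 9 not past the test (median -0.005, between -0.20 and 0.14 on leaving out 1 library, mean 0.18; camera adjusted p = 0.807), with S100B at 3.35 ± 0.29. Adjusted over the list alone, the endothelial counts were 5 and 3, the pericyte counts 2 and 2, and the nerve counts 2 and 1.

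Of 16 T and NK cell genes, 2 were higher, 0 lower and 14 not past the test, with 1 higher adjusted over the list alone (median 1.01, camera adjusted p = 0.187), and PRF1 rose by 3.45 ± 0.74. That list passed without fetal library 1 (adjusted p = 0.0258) and without lamb library 3 (median 1.53, adjusted p = 6.52e-04), while its median was 0.38 without lamb library 1. It also passed with no filter beyond 1 count or the genes of the prefiltered table, and adjusted p ranged from 6.52e-04 to 0.825 over all alternatives. Of 5 B and plasma cell genes, 2 were higher and 3 not past the test, also adjusted over the list alone (median 0.67, but 0.07 without lamb library 1 and 1.44 without lamb library 3; camera adjusted p = 0.379), with CR2 at 1.86 ± 0.41. Of 5 adrenal genes, 1 was higher, 1 lower and 3 not past the test, also adjusted over the list alone (median 0.61, but 0.21 without lamb library 3; camera adjusted p = 0.669). The lower one was CHGA (log2 difference -1.24 ± 0.34), whose call was lost without fetal library 2 (adjusted p = 0.0750) and with scaling by library totals (adjusted p = 0.0807), in a range of 0.00138 to 0.0807 over all alternatives. Of 5 kidney genes, 1 was higher and 4 did not pass, also adjusted over the list alone. Their median was -0.25 and their mean 0.24 (camera adjusted p = 0.774), and the median was 0.49, 0.21 and -0.55 without fetal library 1, 2 or 3. KL rose by 2.38 ± 0.44.

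Of 5 tested mesothelium genes, 4 were lower in lambs and 1 did not pass the test, while 4 were lower and 1 higher adjusted over the list alone (median -2.88, camera adjusted p = 0.0399; adjusted p = 0.682 with an estimated correlation). The 4 were KRT7, UPK1B, UPK3B and KRT8, genes that urothelium expresses too, and WT1 was at 1.30 ± 0.52. The call was lost without lamb library 1 (adjusted p = 0.0531) and without lamb library 3 (adjusted p = 0.0785), and with upper quartile factors or limma-voom, in a range of 8.03e-04 to 0.682 over all alternatives. KRT7 had 806 fetal counts and 1 lamb count, a ratio of 1019 with a 95% counting interval of 182 to 40295. KRT5 had 632 and 1 (ratio 799, interval 143 to 31607) and UPK1A 420 and 2 (ratio 265, interval 73.0 to 2199). UPK3A had 250 fetal counts and 0 lamb counts and was at least 105-fold lower in lambs, set against 3 counts over the group. KRT15 fell by 7.16 ± 0.70. KRT13 fell by 7.13 ± 1.62, but by 4.42 without fetal library 1, which held 787 of its 868 fetal counts, and its call was lost with limma-voom (adjusted p = 0.0940).

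Fetal library 1 held 34 genes at 5 CPM or more that were at least 8-fold above every other library, against 6 in fetal library 2, 0 in fetal library 3, 1 in lamb library 1, 4 in lamb library 2 and 0 in lamb library 3. Among the 34 were genes of pancreatic enzymes, chosen after their values were seen: CPA1 had 14819 counts there and 9 to 14 in the others, and CEL had 13976 against 12 to 27. Of 12 tested skeletal muscle genes, 4 were lower in lambs and 8 not past the test, also adjusted over the list alone (median -1.50, camera adjusted p = 0.156), with the myoglobin gene MB at -5.87 ± 0.59 and CKM at -2.55 ± 0.47. MB, CKM and TNNT1 passed on leaving out any 1 library. The median of the muscle list was 0.07 without fetal library 1, -2.80 without fetal library 2, and -2.38 and -2.53 without lamb library 1 or 2. It was -2.55 without fetal library 3, where the list passed (adjusted p = 0.0208), as it did with library totals, no filter beyond 1 count or the exact test (in a range of 0.0207 to 0.825 over all alternatives). Without fetal library 1, 4970 genes passed the threshold and 4798 of the 6095 calls were kept.

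**Figure D3:**
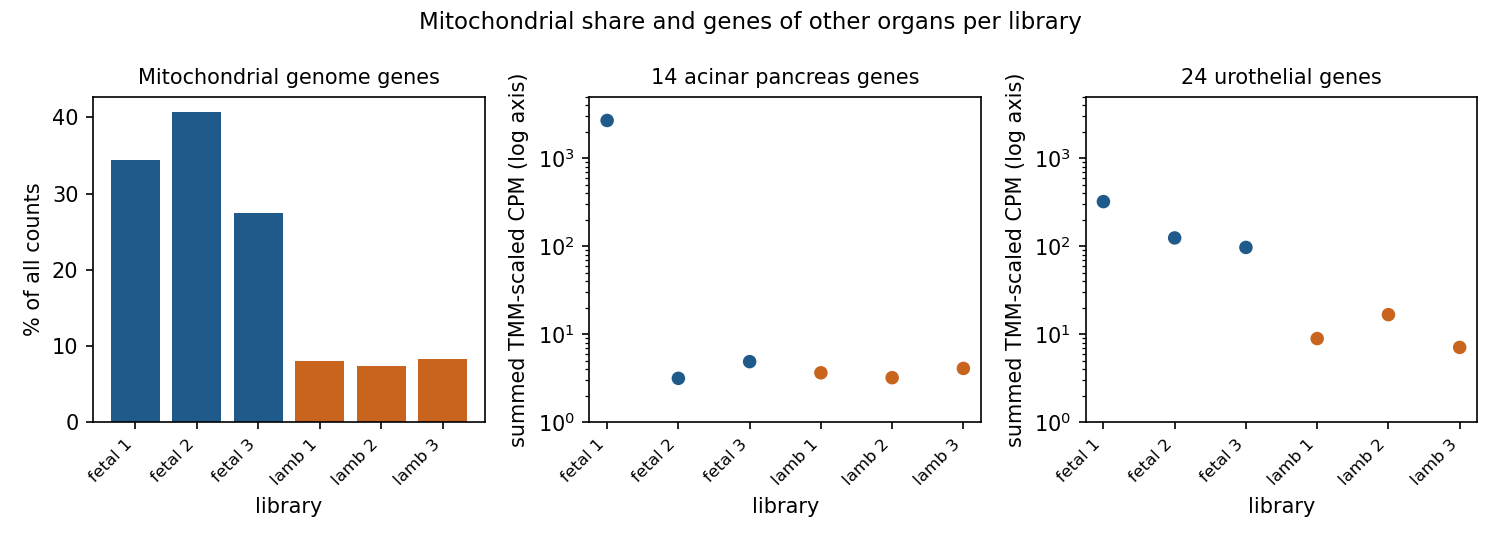
Left, share of all counts in mitochondrial genome genes per library, in percent. Middle and right, summed TMM-scaled CPM of 14 acinar pancreas genes and 24 urothelial genes per library on log axes, fetal in blue and lamb in orange: the pancreas sum is 2672 in fetal library 1 and at most 4.89 in the others, and the urothelial sum is 96.8 to 320 in fetal and 7.10 to 16.7 in lamb libraries.

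Of the 34 lists, 15 passed with camera's preset correlation and 0 with an estimated one, whose smallest adjusted p was 0.513. The fry test, which asks whether a list's genes move on balance one way, called 17 lists: the same ones except extracellular matrix (adjusted p = 0.0506), and also lipolysis and lipid droplets (0.0451), HOX genes (0.00492) and clock genes (0.0451). The edgeR result of the authors called 5429 genes in the full table, 2559 higher and 2870 lower in lambs. Among the 13624 genes tested here it called 5001, of which 4885 were also called here in the same direction and 0 in the opposite one; both results rest on the same counts.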

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

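All tests of an explanation below were chosen after the pattern was seen. The outcomes for pancreas and epithelial genes not yet looked at were still unknown when those tests were set, while the tests of stage expression, of expression by fat cells, of the mitochondrial share and of the fat cell share, and the split counts of genes called, were set with their values seen.

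A signal stood in columns that the comparison does not use: 784 genes with 0 counts in all 6 libraries had a mean RPKM of the authors above 0 in at least 1 stage. Of these, 375 have an identifier only, and 129 reached an RPKM of 1 or more in a stage. The largest was ENSOARG00000016755 (chromosome 12, 26197057 to 26745107), with 5436.2 RPKM in fetuses and 1211.6 in lambs. The largest with a symbol was BHLHE23, with 69.0 in fetuses and 153.1 in lambs. Groups of 3 libraries were not tested for outliers.

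Pancreatic enzyme genes stood out in fetal library 1. The summed level of 14 acinar genes was 2672 CPM there, 0.233% of its counts (95% Wilson interval 0.231 to 0.236%), and 3.16 to 4.89 CPM in the other 5 libraries. Fetal libraries 2 and 3 did not share that level, the higher of them being at 1.338 times the lamb mean. The 14 genes were picked after these values were seen, so the ratio does not test expression by perirenal fat at the fetal stage. Pancreatic tissue or RNA in fetal library 1 is a candidate explanation that stays open. Of 6 further pancreas genes with 10 or more counts, only 2 (PDIA2 and SERPINI2) were at least 8-fold above every other library there, and 0 in each other library. That lies between the bounds set for and against it. The most abundant were ENSOARG00000006600, with no symbol, at 90735 counts against 29 to 59, and CPA1 and CEL, and the lipase gene PNLIP had 0 counts there.

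The sum of 24 urothelial genes picked after their values were seen was higher in all 3 fetal libraries. The genes, 4 of which are in a list fixed beforehand, summed to 320, 124 and 96.8 CPM against 8.94, 16.7 and 7.10 CPM in lambs. Of 22 further epithelial genes with 20 or more counts, 15 were higher in every fetal than in every lamb library and 1 the other way, where chance gives 5% for 1 direction and 29.5% of all tested genes were higher in every fetal library. All 28 further epithelial genes with at least 1 count summed to 342, 279 and 261 CPM in fetuses and 226, 239 and 257 CPM in lambs, a far smaller difference than that of the picked genes. LLGL2 was the 1 gene higher in every lamb library. Of the abundant ones, MAL2 and ITGB4 did not separate the stages, while LAMA3 and LAMB3 were higher in every fetal library. The count of 15 of 22 is consistent with epithelial tissue of another organ carried with the fetal fat. Expression by the fetal fat cells themselves cannot be told apart from it, because the test rests on 1 library: in fetal library 1 against the other 2 fetal ones, the urothelial genes lay 1.47 log2 units above the general adipocyte genes (medians 1.315 and -0.155, quartiles 0.95 to 1.597 and -0.411 to 0.018). A difference by age in epithelium that belongs to the depot was not tested.

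The respiratory chain genes fell as a set. Mitochondrial genome transcripts taking a large share of the fetal counts are argued against as the whole cause, since scaling by library totals leaves that share uncorrected, which raises all other genes in lambs, and the median log2 difference of the 55 nuclear respiratory chain genes was still -1.51 there (quartiles -1.904 to -1.198). A lower share of fat cells in the lamb samples would lower the general adipocyte genes. Their median was 1.39, between 1.051 and 1.402 on leaving out 1 library. That cannot exclude a lower share, because their levels per cell may differ by stage. Members moved unequally, FABP4 by 2.83 and SLC2A4 by -2.02, and the macrophage and fibroblast lists rose too (medians 1.16 and 0.65). A difference by age, which the design names, stays open and was not tested.

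Of the 10 splits of the 6 libraries in 3 and 3, the number with a result as large, the real one included, was 1 for genes called, 1 for genes called at more than 2-fold, 3 for lists called by camera and 1 for the F of UCP1. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes the stages within its groups, so the stage difference enters the spread within groups. Few gene calls and a low F of UCP1 were therefore to be foreseen there, whatever their cause. The groups of those splits remain unbalanced by stage, so their camera counts are not a rate under no change. The real split called 6095 genes with edgeR and the highest of the others 0, with at most 290 genes at an unadjusted p under 0.05 against 7224. Above 2-fold the counts were 3122 and 0. The F statistic of UCP1 was 44.4 against 2.95. Camera with its preset correlation called 15 lists in the real split and 7 to 16 in the others, while fry called 17 and 0.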

How the results depend on the processing

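No call of a gene or list named in the text changed direction under any alternative run, and 0 of the 6095 genes called did. Leaving out 1 library gave 4798 to 5654 genes called, 2286 to 2796 higher and 2512 to 2903 lower in lambs, with 2807 to 3193 beyond 2-fold, 1183 to 1399 of them higher and 1624 to 1794 lower, and UCP1 between -1.997 and -1.52. With library totals only, the count of genes higher in lamb was 5598, of genes lower in lamb 1459, of genes more than 2-fold higher in lamb 2960 and of genes more than 2-fold lower in lamb 988. The construction of that setting shows why: the share of counts outside the mitochondrial genome alone differs by 0.49 on the log2 scale between the stages, and the median of all genes moved by 0.47. With an estimated inter-gene correlation 0 lists passed, and the brown adipocyte list, with its median of -1.78, had adjusted p = 0.563. Over the other genes and lists named by rule, leaving out 1 library ended a call in 68 gene and 3 list cases and made one in 2 and 7. The other settings ended a call in 31 gene and 20 list cases and made one in 7 and 13. Of the 20, 14 arose in the setting with an estimated correlation, which has little power here. The cause of the changes was not tested. Replicate numbers gave no sign of pairing across all genes: the correlation of deviations from the stage mean was 0.003, -0.12 and 0.05 for equal numbers. A factor shared by some genes is not excluded, since SCD and FASN were highest in library 3 of both stages. Leaving out the mitochondrial genome genes (6125 genes called) and the genes of fetal library 1 alone (6105) were chosen after seeing the data. Alternatives for tables with RPKM only were not run. With only 200 genes simulated as changed, which makes the adjusted threshold stricter than in the real comparison, increases of 2-fold were found in 32.5% and those of 1.5-fold in 0%.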

Other observations

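The tests of splits and explanations stand above, and none is added here; every gene in this part that the rule did not name was chosen after its values were seen. RBP4, the plasma carrier of retinol, rose from 26.7 ± 5.61 to 1045 ± 202 CPM (log2 difference 5.29 ± 0.25, adjusted p = 3.09e-05), and TAC1, the precursor of substance P, from 0.970 ± 0.234 to 59.2 ± 32.8 CPM (5.94 ± 0.50). LHR, the receptor of luteinizing hormone, fell from 13.7 ± 1.55 to 0.151 ± 0.0986 CPM (log2 difference -6.44 ± 0.36), alongside PRLR. The deiodinase genes DIO1 and DIO2 fell, while the thyroid hormone receptor gene THRB, listed as ERBA BETA1, rose by 0.92 ± 0.14 (adjusted p = 0.00177).

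Among genes of plasma proteins, ALB rose from 56.3 ± 45.2 to 542 ± 223 CPM (log2 difference 3.27 ± 0.64, adjusted p = 0.00499) and TF from 20.5 ± 6.61 to 122 ± 38.2 CPM (2.58 ± 0.31), whereas FGA was at 8.98 CPM in fetal library 2 and at most 0.311 CPM in the others. Among single heat shock genes, HSPH1 rose by 1.93 ± 0.22, and HSPA6 was at 0.832 ± 0.0993 CPM in fetuses and at 16.7, 109 and 12.8 CPM in the lamb libraries, whereas HSPA8 did not pass the test (log2 difference 0.26 ± 0.19, adjusted p = 0.294).

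SCD and FASN varied within both stages. SCD was at 3213, 2612 and 6006 CPM in fetal libraries 1, 2 and 3 and at 732, 960 and 3861 CPM in lamb libraries 1, 2 and 3, FASN at 754, 676 and 3315 CPM and at 792, 581 and 2029 CPM, and neither passed the test between stages (adjusted p = 0.201 and 0.603). Among lambs, LEP, at 11.3 ± 12.2 CPM, was highest in library 3 too.

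More epithelial genes had nearly all their counts in fetal libraries. CLCA2 had 217 fetal and EPCAM 203 fetal counts, each with 0 lamb counts, and UPK2 had 231 and 3. Genes of fetal library 1 alone also included SST with 114 counts against 0 or 1, the plasma protein precursor gene AMBP with 562 against 0 to 45, and the muscle genes ACTA1 with 542 against 8 to 64 and MYLPF with 166 against 0 to 2. The pancreas genes CPA1, CEL, PNLIPRP2 and CELA1 passed the test between stages, with adjusted p from 0.0368 to 0.0444, although fetal libraries 2 and 3 did not stand above all lamb libraries.

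The RPKM means of the authors and the counts did not always give the same picture. Of 6086 called genes with both, 243 differed by more than 1 log2 unit between the ratio of RPKM means and the ratio of mean counts scaled by library totals, and 232 had opposite signs. UCP1 was 1.86-fold higher in fetuses by RPKM (1315.1 and 705.7) and 2.39-fold higher by counts scaled by library totals (3.43-fold with TMM). LEP was 1.69-fold higher in fetuses by RPKM (49.5 and 29.2) and at 0.736 of the lamb level by counts scaled by library totals (log2 difference -0.003 with TMM).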
